A study of Mus musculus with 2 samples.

How the data were processed

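H3K36me3 was mapped by ChIP-seq in whole stomach of newborn mice (postnatal day 0, males and females pooled), in 2 biological replicates of a single group. Group and replicate were taken from the labels. Each replicate is 1 library from its own tissue pool, so spread between them holds both biological and technical differences.

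The analysis started from 4 lists of peaks on the mm10 assembly, per the labels and the notes deposited with them. One list was called on replicate 1, one on replicate 2 and one on both together. The fourth is a list of replicated peaks that, per the deposited notes, derives from the other three, and every one of its peaks has the position of a peak of the list called on both. The peak caller, the aligner, the thresholds and the rule for replication are not given in the sources used here. Those notes name one more input entry for the list of replicate 1 than for that of replicate 2, without saying what it holds. Each peak has a display score set by the authors, which was not used. Each also has a signal value, read as a ratio or fold enrichment by the authors' peak caller, whose background the lists do not state. The deposited −log10 p and −log10 q of each peak were used to rank and filter peaks within a list. The smallest −log10 p was 2.05 in replicate 1 and 2.02 in replicate 2. In replicate 1 92.9% of peaks had a q under 0.05, and in replicate 2 3.36%, with a median −log10 q of 0.504. The list of replicate 2 is therefore permissive. Read numbers are not part of the lists, so depth per sample is unknown, and a region with no peak may still carry the mark below the authors' threshold.

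Coordinates are 1-based on mm10. Genes came from GENCODE mouse release M21, which uses the same assembly: 0 peaks lay past a chromosome end. Peaks on chromosomes 1 to 19, X and Y were used, which left out 15 peaks of replicate 1, 7 of replicate 2, 14 of the list of both and 8 replicated peaks on other contigs. Of 21911 protein-coding genes, 20327 of at least 2 kb were tested, after leaving out 27 repeated symbols. Of these, 10575 overlap no other annotated gene. A gene was called marked when at least 10% of its body, from annotated start to end, was covered by peaks. Gene bodies can overlap and peaks have no strand, so shared coverage counts for each gene.

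Overlap of peaks (at least 1 bp) and the share of peak bases in gene bodies were set against 100 random placements of the peaks on the same chromosome, with assembly gaps (78.0 Mb) left out. For 32 lists of genes, the number of marked members was set against 10000 random lists of the same size in the same classes of gene length (10 classes). The two-sided permutation p was adjusted by Benjamini-Hochberg over the 32 lists. The lists were stomach cell types, housekeeping groups, other organs, HOX genes, imprinted genes, olfactory receptors and zinc finger genes with Zfp symbols. In them 5 symbols matched no protein-coding gene (Mrg15, H19, Kcnq1ot1, Meg3 and Amy2b), and 125 matched members, 97 of them olfactory receptors, were not tested because they are shorter than 2 kb. Smooth muscle and mesenchyme genes were compared with epithelial genes (the general, mucous, parietal and chief cell lists) by two-sided Fisher's exact test, as were X-linked and autosomal genes. The last and first of 3 equal parts of marked genes of at least 10 kb were compared by 100000 sign flips over genes. Coverage of exons over introns was compared with 100 circular shifts of the peaks within each gene. Shares of genes carry exact Clopper-Pearson 95% intervals. Genes and peaks are not replicates, so these p-values describe the libraries.

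Genes named in the text followed a rule set before the data were examined: the 20 most covered genes of at least 10 kb marked in both replicates, up to 4 members of each list with the most and 2 with the least coverage, the 5 peaks with the highest signal value and the 5 widest, the 5 longest intergenic stretches with peaks merged within 3 kb, and the 5 most covered genes of at least 10 kb marked in one replicate with no peak in the other. Other genes are said to have been chosen after their values were seen.

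The steps were tested on simulated data. Of 200 genes given peaks over 30% of their length, 200 of 200 were marked, and 372 other genes, some of which overlap those, were marked by these or by randomly placed peaks among the 20327 tested. A list seeded with such genes had an adjusted permutation p of 0.0082 over 41 lists, and 0 of 40 random lists passed. Far fewer genes were marked here than in the data (4025). The simulation therefore does not give the error rate of the list test there, nor its power to find lists below chance. In a simulation with 200 genes, peaks placed late in the gene passed the exon permutation test with shifts along the whole gene (p = 0.0198) but not with shifts within each of 5 equal parts (p = 0.416), and peaks placed on exons passed both.

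Alternatives tried were a −log10 q of at least 5, the list called on both replicates, each replicate left out by using the other's own list, marking at 5% and 20%, genes that overlap no other gene, no minimum gene length, genes of at least 30 kb for the profile, exons only, medians in place of counts, peak midpoints, overlap of at least 50%, and the same number of peaks (the strongest) from each replicate for the overlap. Replicated peaks that overlap both replicates' lists, random lists matched on GC content as well as length (5 classes each), autosomal genes only and shifts within 5 equal parts of the gene were added after the data were seen. So was a comparison of the replicate 2 coverage of list members marked in replicate 1 (lists with at least 10 of them) with 10000 sets of other genes in the same class of replicate 1 covered share (10 classes) and of gene length, GC content or strongest peak (5 classes). Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.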

Results

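H3K36me3, trimethylation of histone H3 at lysine 36, is a chromatin mark that is known to be laid down over the bodies of genes as RNA polymerase II transcribes them. It was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole stomach of newborn mice on postnatal day 0, in tissue pooled from males and females. The series holds 2 samples of a single group, biological replicates 1 and 2, each a separate tissue pool. The labels give 15 mice for replicate 1 and no number for replicate 2. The values are lists of peaks, stretches of the genome that the authors called as enriched: 133755 peaks for replicate 1, 31598 for replicate 2, 119024 for both together and 65412 that the authors list as replicated. Read numbers are not given in these lists, so sequencing depth is unknown. With 1 group there is no contrast between conditions. The design asks how far the replicates gave the same peaks, which genes carried the mark, and where along genes and chromosomes it lay.

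Overlapping sets of genes carried the mark in both stomach pools, but replicate 2 gave far fewer peaks. Replicate 1 held 4.23 times as many peaks as replicate 2 and 5.55 times as many bases, 42.5 Mb against 7.66 Mb. Of 601 protein-coding genes marked in replicate 2, meaning that peaks covered at least 10% of the gene body, 599 were also marked in replicate 1, where 5181 genes were marked. Independent lists of these sizes would share 153. The other 2 genes, named after their values were seen, were Med18 and Atpif1 on chromosome 4, with 9.03% and 6.76% covered in replicate 1. Across 10939 genes with a peak in either replicate, the covered shares had a Spearman rho of 0.759 and a Pearson r of 0.783. These are correlations across genes, which are not independent replicates.

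Peak by peak, 71.2% of the replicate 2 peaks (22489 of 31591) overlapped a replicate 1 peak by at least 1 bp. Random placements of the peaks on the same chromosomes gave 3.18% on average and at most 3.45% in 100 draws. In the other direction 16.6% of the 133740 replicate 1 peaks were shared, against 0.754% at random. Both shares lay above all 100 placements (two-sided permutation p = 0.0198, the smallest that 100 placements can give). The placements spread over whole chromosomes, while 95.5% and 96.7% of the replicates' peak bases lay in protein-coding genes. No placement was kept within marked genes, so the test does not show that positions match within genes. Of the peak bases, 56.5% of those in replicate 2 lay inside replicate 1 peaks, and 10.2% the other way round. The shared part of replicate 1 grew with peak strength: of 10 equal classes by the deposited p, 7.54% of the weakest and 38.3% of the strongest overlapped replicate 2. With overlap of at least 50% of both peaks required, the shares were 25.7% and 6.08%. With the same number of peaks taken from each replicate, the strongest 31591, they were 34.6% and 30.6%. The replicated list leaned on replicate 1: 31.9% of its 65404 chromosomal peaks overlapped both replicates' own lists, 55.8% overlapped replicate 1 alone, 5.11% replicate 2 alone and 7.15% neither. Only 11.8% had at least 50% of their length covered by each replicate's list.

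**Figure D1:**
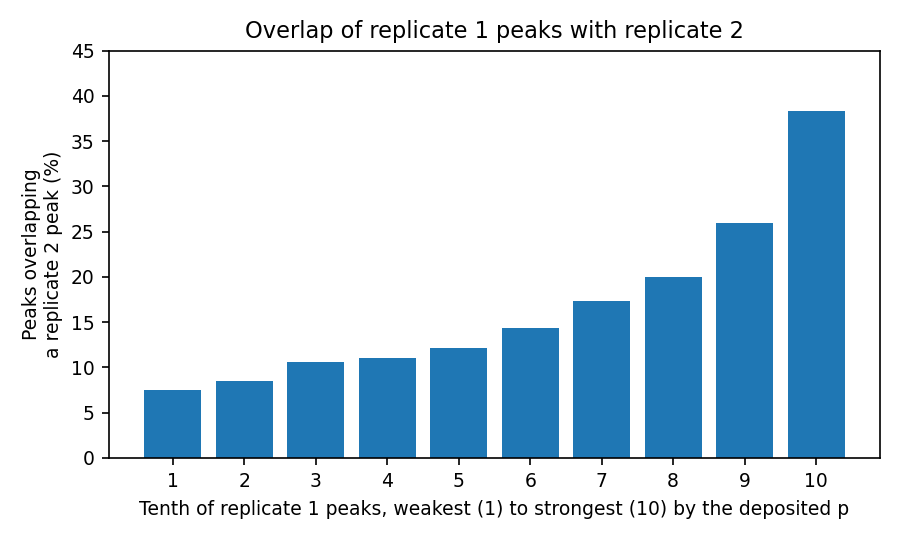
Share of replicate 1 peaks that overlap a replicate 2 peak by at least 1 bp (%, y axis), for 10 equal classes of replicate 1 peaks from weakest to strongest by the deposited p (x axis); each bar is 13374 peaks of 1 library. The share is 7.54% in the weakest class and 38.3% in the strongest.

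Of genes of at least 10 kb, 216 were marked in replicate 1 with no peak in replicate 2, and 0 the other way round. The 5 with the largest covered share in replicate 1 were Gtse1 (37.7%), a regulator of the cell cycle, Snrpc (34.1%), a part of the U1 splicing particle, Coq9 (33.3%), which serves coenzyme Q synthesis, Aurka (33.1%), a mitotic kinase, and Xrcc3 (32.9%), a DNA repair gene. Given how many more peaks replicate 1 has, these counts do not show a difference between the tissue pools.

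H3K36me3 lay almost entirely inside protein-coding genes. Of the bases in replicated peaks, 96.5% fell between the annotated start and end of a protein-coding gene, against 42.3% (41.6% to 42.8%) for random placements (two-sided permutation p = 0.0198, the smallest possible). The replicates' own lists gave 95.5% and 96.7%, a mean of 96.1% ± 0.862 (SD, n = 2). Only 1861 replicated peaks (2.85%) lay outside every annotated gene. The 5 longest intergenic stretches, with peaks merged within 3 kb, all began close to the end of a gene, on its downstream side. They ran 50 bp past Ppp4r1 (6382 bp, chromosome 17, 65841977 to 65848358), 135 bp past Pars2 (6201 bp), 78 bp past Zfp146 (5686 bp), 246 bp past Ppia (5553 bp) and 84 bp past Trim24 (5260 bp). Replicate 1 held peaks in all 5 stretches. Replicate 2 covered 0% of those at Pars2 and Trim24.

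By the rule that at least 10% of the gene body is covered by replicated peaks, 4025 of 20327 protein-coding genes of at least 2 kb (19.8%) were marked, with a median of 19.8% of the body covered. Of these, 3425 did not reach 10% in replicate 2 alone. The most fully covered genes of at least 10 kb that were marked in both replicates were led by Fasn, fatty acid synthase, at 74.3% of its 18.7 kb on chromosome 11 (120805846 to 120824547). Its covered share was 65.5% in replicate 1 and 28.5% in replicate 2. Genes of chromatin and transcription among the top 20 were Kmt2b (66.4%) and Kmt2d (65.7%), which methylate histone H3 at lysine 4, and the gene of the nuclear matrix protein Safb (63.1%). RNA processing was represented by Prpf8 (65.7%), a core part of the spliceosome, Pcif1 (68.4%), which methylates the cap of messenger RNA, Cherp (66.8%) and the RNA helicase Ddx39b (62.9%). Tln1 (66.7%), which links integrins to actin, Scrib (66.2%), a cell polarity gene, and Flii (63.3%) are genes of cell shape. Ribosome production and translation were represented by Nol6 (64.4%), Mybbp1a (63.2%) and Eif3d (62.0%), and the circadian clock by Per1 (65.2%). The others were Hjurp (73.3%), which loads centromeric histone, Prrc2a (66.6%), Leng8 (65.5%), Atxn2l (63.4%) and Akap8 (63.1%). Across the 20 genes, replicate 1 covered 41.0% (Mybbp1a) to 74.6% (Hjurp) and replicate 2 covered 10.2% (Nol6) to 56.6% (Hjurp). Apart from Hjurp, the highest were 65.5% (Fasn) and 40.8% (Prrc2a). A wide peak over part of Hjurp had a deposited p far from that of other peaks of like signal value (below). How reads of uncertain placement were treated there is not shown, so the coverage of Hjurp may not reflect H3K36me3. Peaks carry no strand, so for Pcif1, Cherp, Tln1, Prrc2a, Scrib, Leng8, Flii, Mybbp1a, Ddx39b and Eif3d, which overlap another annotated gene, the coverage cannot be assigned to 1 gene. At a deposited −log10 q of at least 5 the count of marked genes fell to 166, and in replicate 2 alone it was 601.

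The replicated peak with the highest signal value was also the widest, over Plec, which encodes the cytoskeletal linker plectin. It covered 13098 bp of exons and introns on chromosome 15 (76170398 to 76183495), with a signal value of 7.97. The next highest signal values were at 2610008E11Rik on chromosome 10 (79066702 to 79067931, in an exon, 7.37), at the chromatin remodelling gene Smarcc2 on chromosome 10 (128482094 to 128483561, 7.23), at Zfp68 on chromosome 5 (138606237 to 138607895, 7.23) and in introns of Ccdc106 on chromosome 7 (5028930 to 5032570, 6.93), a stretch shared with Zfp865. Other wide peaks ran from the end of Mroh2a into Hjurp on chromosome 1 (88261009 to 88270280, 9272 bp), over Per1 on chromosome 11 (69101640 to 69109861, 8222 bp), over Zfhx3 on chromosome 8 (108946225 to 108952707, 6483 bp) and over Mbd1 on chromosome 18 (74273106 to 74278535, 5430 bp). All of these held exons and introns. Signal values are the authors' own per-peak values and serve here to rank peaks within the list.

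Genes of basic cell functions carried the mark far more often than genes of equal length. Of 40 splicing factors 34 were marked, against 9.20 in random lists matched on gene length. The proteasome had 25 of 31 (7.15 expected), ribosomal proteins 35 of 49 (6.97), the respiratory chain and TCA cycle 27 of 38 (8.70), and cell cycle and DNA replication 21 of 38 (8.93). The writers, erasers and readers of H3K36 methylation itself had 18 of 26 (4.71). For each of these 6 lists the two-sided permutation p was 0.0002, the smallest that 10000 random lists can give, and 0.0008 after Benjamini-Hochberg adjustment over 32 lists. Examples were Prpf8 (65.7% covered), Sf3a1 (56.5%), the proteasome subunits Psmd3 (56.3%) and Psmd7 (55.6%), Rps7 (46.5%) of the small ribosomal subunit, the ATP synthase subunit Atp5a1 (50.1%), the condensin subunit Ncapd2 (33.6%), and the demethylase Kdm4a (55.7%). Psmd3, Atp5a1, Ncapd2 and Kdm4a overlap another gene. Members without a replicated peak included Rps27a, Psmb4, Snrpf, Pcna, Dnmt3b and the X-linked Rps4x, Idh3g, Pdha1 and Pola1. In replicate 2 alone, splicing factors (11 marked), ribosomal proteins (8) and the proteasome (6) passed, with adjusted permutation p of 0.00213, 0.0064 and 0.0102. The other 3 lists did not pass there, with 5, 3 and 0 marked members and adjusted permutation p of 0.111 for the respiratory chain, 0.0885 for the H3K36 list and 1 for the cell cycle list. The cell cycle list also failed at 20% of the body (8 marked, adjusted permutation p = 0.380) and with only peaks that overlap both replicates (4 marked, 4.19 expected).

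Zinc finger genes with a symbol of Zfp and a number were also marked above chance, 138 of 364 against 87.8 expected (adjusted permutation p = 0.0008), and 32 against 14.1 in replicate 2 alone (0.00213). Zfp869 (74.9%), Zfp335 (59.8%), Zfp606 (52.1%) and Zfp90 (49.9%) had the largest covered shares, while Zfp994 and Zfp995 had none. Zfp335 and Zfp90 overlap another gene. Reads from near-identical members of this family may not have been placed with certainty, and the lists do not show how such reads were treated.

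Marker genes of the stomach's own cell types were rarely marked at the 10% rule. Over the 13 stomach lists 16 of 223 genes (7.17%) were marked, against 160 of 222 genes (72.1%) on the housekeeping lists. General gastric epithelium had 0 of 21 marked (3.99 expected), surface mucous and gland neck cells 0 of 17, parietal cells 0 of 16 and forestomach squamous epithelium 0 of 15. Chief cells had 1 of 11, Lrig1 (13.2%), and enteroendocrine cells 1 of 17, the ghrelin gene Ghrl (34.2%). Lrig1 and Ghrl overlap another gene. Enteric neurons and glia had 0 of 22, endothelium 0 of 17, blood and immune cells 0 of 18, mesothelium 0 of 10 and interstitial cells of Cajal 0 of 7. None of these 11 lists passed the test, with adjusted permutation p from 0.0507 (gastric epithelium) to 0.612 (interstitial cells). With random lists matched on GC content as well, 5 of them lay below chance: gastric epithelium (0.0165), enteric neurons and glia (0.0178), endothelium and blood and immune cells (0.0344 each) and parietal cells (0.0439). In replicate 1 alone enteric neurons and glia (0.0143), endothelium (0.0243) and mucous and neck cells (0.0253) lay below chance. In replicate 2 alone none did, but there only 0.0825 to 0.631 marked members were expected per list, too few for the test to show a deficit. Members with partial coverage included the chief cell gene Rab3d (8.998%), the epithelial transcription factor Klf5 (8.99%), the membrane linker Ezr (8.11%), Cx3cr1 (9.77%) of macrophages and Egfl7 (8.03%) of endothelium. The annotated body of Cx3cr1 is a long stretch of chromosome 9 (119901616 to 120069879), so its coverage may belong to other genes there. The genes of gastric products were listed without any replicated peak for pepsinogens (Pgc, Pga5) and trefoil factors (Tff1, Tff2), and Muc6 had 4.67% covered.

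Smooth muscle had the highest share of the stomach lists, 9 of 24 marked against 4.28 expected. That did not pass after adjustment (permutation p = 0.0573), though in replicate 1 alone, with 12 marked, it did (0.0154), as it did with the list called on both replicates (13 marked, 0.00587), at 5% of the body (12, 0.0317) and with exons only (14, 0.00457). In replicate 2 alone 2 were marked (adjusted permutation p = 0.813). With random lists matched on GC content as well the value was 0.169, and with only peaks that overlap both replicates 0.254. At 20% of the body (5 marked) the adjusted permutation p was 0.305, and among genes that overlap no other gene (4 marked) it was 0.483. Its best covered members were Smtn (43.3%), Tpm1 (33.1%), Srf (29.2%) and Tpm2 (25.6%), which encode smoothelin, the contractile tropomyosins and a regulator of muscle genes. Smtn and Srf overlap another gene. Gastric mesenchyme and fibroblasts had 5 of 30 (5.12 expected, adjusted permutation p = 1), led by the collagen gene Col1a1 (42.7%), the hedgehog receptor Ptch1 (24.1%), Col6a1 (16.8%) and fibronectin, Fn1 (14.9%). Ptch1 and Fn1 overlap another gene.

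Few genes of other organs and no HOX gene or olfactory receptor passed the 10% rule. Of 185 genes on 9 lists of other organs, 2 were marked (1.08%): Ager (21.6%) of the lung list and Nr1i3 (14.4%) of the liver list, which overlaps another gene. A replicated peak of any size lay in 10 of the 185, and a replicate 1 peak in 28. Skeletal and cardiac muscle (0 of 26, 4.72 expected) and testis and germ line (0 of 23, 4.67 expected) lay below chance (adjusted permutation p = 0.0314 for both). The 7 other lists did not pass, with adjusted permutation p from 0.0532 (brain, 0 of 25) to 0.463 (lung, 1 of 15). Intestine (0 of 18), pancreas (0 of 18), kidney (0 of 18), retina and lens (0 of 20) and liver (1 of 22) lay between them. With matching on GC content as well, brain (0.0134), kidney (0.0209), retina and lens (0.0276), pancreas (0.0335) and intestine (0.0349) lay below chance. In replicate 1 alone all of these and liver did, with adjusted permutation p from 0.0143 to 0.0209. HOX genes had 0 of 38 marked (6.40 expected, adjusted permutation p = 0.00782) and olfactory receptors 0 of 1037 (190.7 expected, 0.0008). Matched on GC content as well, 38.0 olfactory receptors were expected. Imprinted genes had 1 of 21, Impact (10.6%), which overlaps another gene, with an adjusted permutation p of 0.191. Genes are not replicates, so the tests on lists describe these libraries. In replicate 2 alone only olfactory receptors lay below chance.

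**Figure D2:**
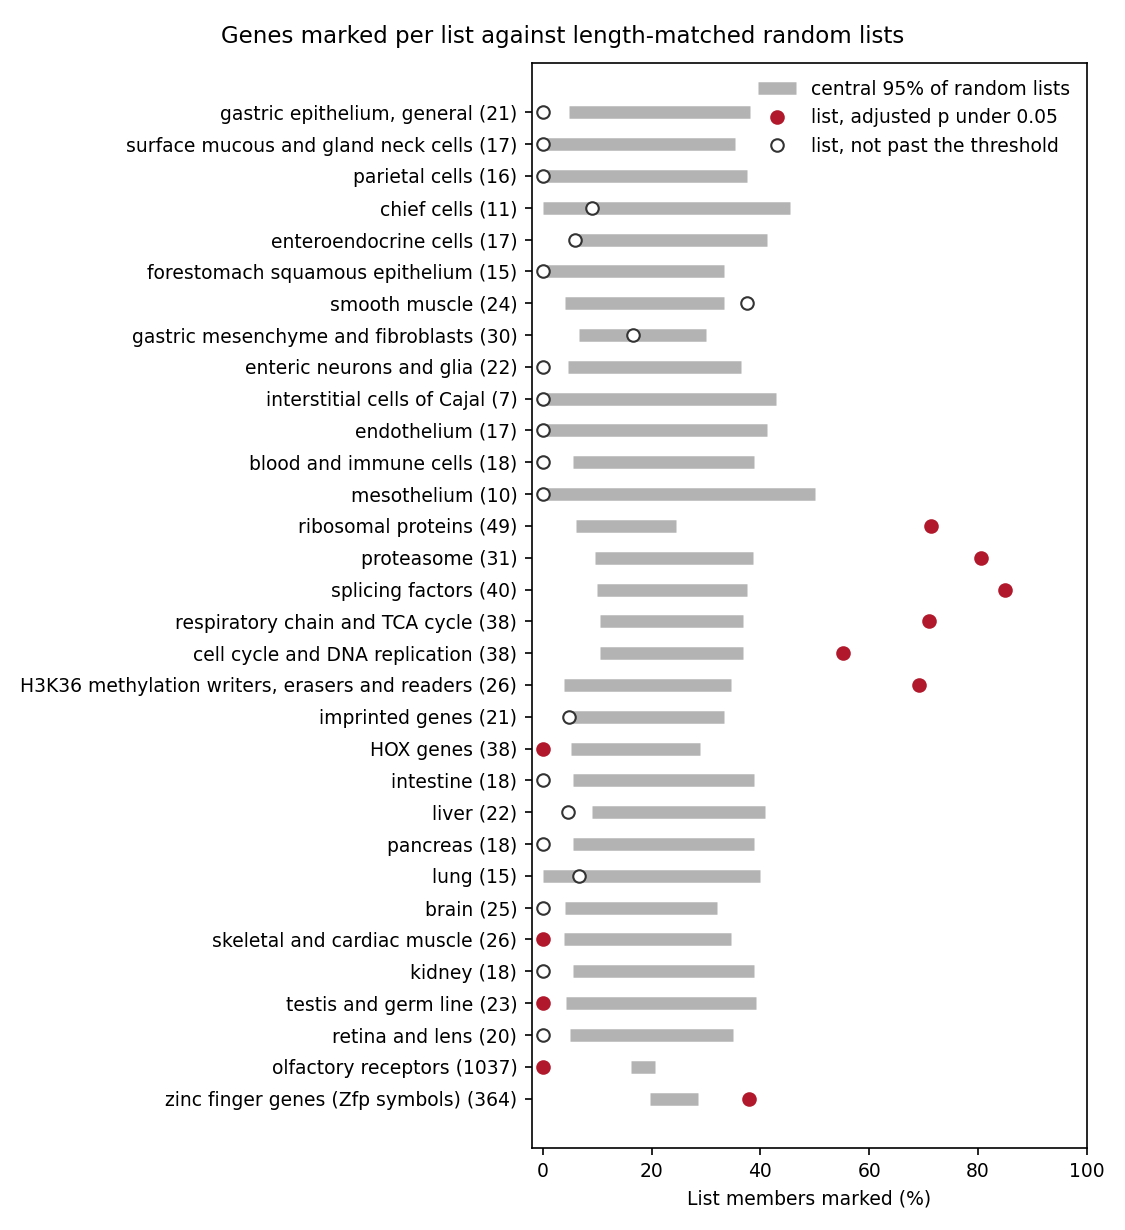
Members marked (%, x axis) for each of 32 gene lists (y axis, number of genes tested in brackets), where marked means at least 10% of the gene body covered by replicated peaks. Points are the lists, filled where the adjusted permutation p is under 0.05, and grey bars span the central 95% of 10000 random lists matched on gene length. The housekeeping lists lie between 55.3% and 85.0%, and olfactory receptors at 0%.

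Genes of the muscle and connective tissue layers were marked more often than genes of the glandular epithelium. Of 54 smooth muscle and mesenchyme genes 14 (25.9%) were marked, against 1 of 65 epithelial genes (1.54%), a difference of 24.4 percentage points (two-sided Fisher's exact test, p = 0.000103). In replicate 1 alone 21 and 4 genes were marked (exact p = 2.23e-05). In replicate 2 alone 2 and 0 were marked, which the same exact test did not separate (p = 0.204). At a −log10 q of at least 5 none of these genes was marked.

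The mark rose along most of the gene and fell off before its end. Gene bodies were cut into 3 equal parts. In 2994 marked genes of at least 10 kb, replicated peaks covered 8.72% of the first part and 34.1% of the last on average. The mean difference was 25.3 percentage points (sign-flip permutation test of the mean over genes, two-sided p = 1e-05, the smallest that 100000 flips can give). The median difference was 24.7 points, and the last part was covered more in 89.8% of genes. In the replicates' own lists the median difference was 21.3 and 15.5 points, a mean of 18.4 ± 4.07 (SD, n = 2), over the genes marked in each. In 1304 of these genes that overlap no other gene, coverage was 0.0767% in the last 500 bp before the gene start. It reached 37.7% shortly before the gene end, dropped to 26.4% in the last of 20 bins of the gene body and was 16.3% in the first 500 bp past it. The replicates' own lists showed the same drop, from 36.7% to 27.6% and from 9.87% to 6.80%.

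**Figure D3:**
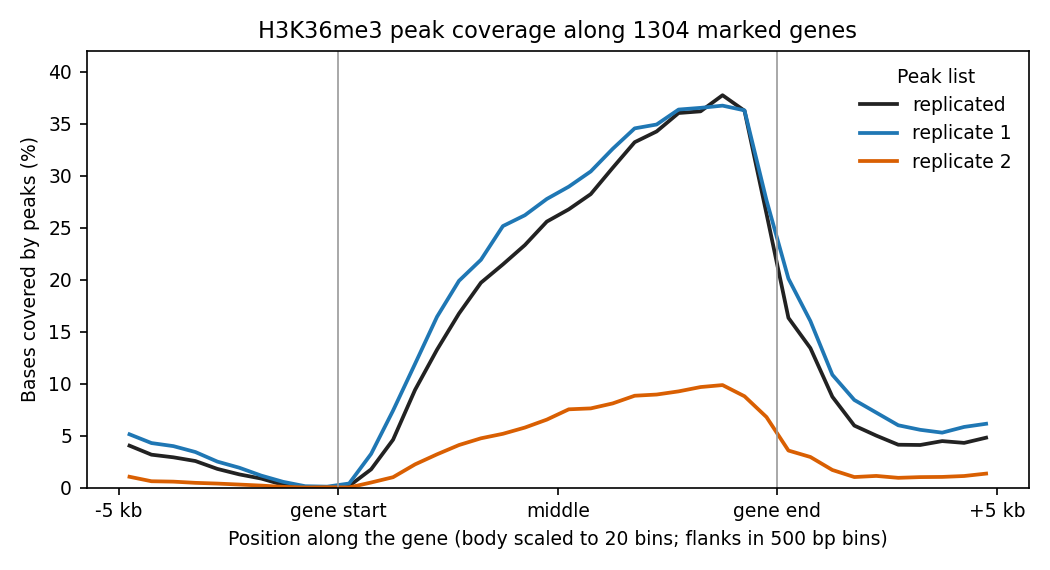
Bases covered by peaks (%, y axis) along 1304 marked genes of at least 10 kb that overlap no other gene, with the gene body scaled to 20 bins and 5 kb on either side in bins of 500 bp (x axis). Lines show the replicated list and each replicate's own list, over the genes marked in the replicated list; the replicated line rises from 0.179% at the gene start to 37.7% near the end.

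Exons were covered more than introns. In the 4025 marked genes, replicated peaks covered 33.5% of exonic and 17.5% of intronic bases, a ratio of 1.92. When the peaks were shifted around each gene at random the ratio was 1.13 (1.11 to 1.16), and 0 of 100 shifts reached the observed value (two-sided permutation p = 0.0198, the smallest possible). Shifting peaks only within each of 5 equal parts of the gene, an alternative added after the data were seen, gave a mean of 1.51 and at most 1.53, below 1.92 in all 100 shifts. The ratio was 1.77 in replicate 1 and 1.75 in replicate 2, a mean of 1.76 ± 0.0103 (SD, n = 2). These are over the genes marked in each, 5181 and 601, so the SD is not the spread of the ratio over the same genes. Single genes varied: of the 20 most covered genes above, the clock gene Per1 (94.8%) and the splicing gene Prpf8 (90.4%) had the highest shares of exonic bases covered, while in 6 of the 20 exons were covered less than the whole gene, most of all in Ddx39b (51.2% against 62.9%).

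The X chromosome was nearly empty of H3K36me3 peaks. Of 791 X-linked protein-coding genes 3 were marked (0.379%, exact Clopper-Pearson 95% interval 0.0783% to 1.10%), against 4022 of 19385 autosomal genes (20.7%, 20.2% to 21.3%), a difference of −20.4 percentage points (two-sided Fisher's exact test, p = 1.64e-72). The 3 genes, named after their values were seen, were Kdm5c (17.4% covered), which demethylates histone H3 at lysine 4, the cold-induced RNA-binding gene Rbm3 (11.2%), which overlaps another gene, and Gm21887 (10.2%). Replicate 1 alone had 11 marked X-linked genes (1.39%) against 26.7% of autosomal genes, and replicate 2 alone had 0 (exact 95% upper limit 0.465%), against 3.10%. Autosomes ranged from 13.6% of genes marked on chromosome 14 to 27.1% on chromosome 8. Of the 65404 replicated peaks 97 lay on X. On Y 0 of 151 genes were marked. Intervals cover counting error only.

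**Figure D4:**
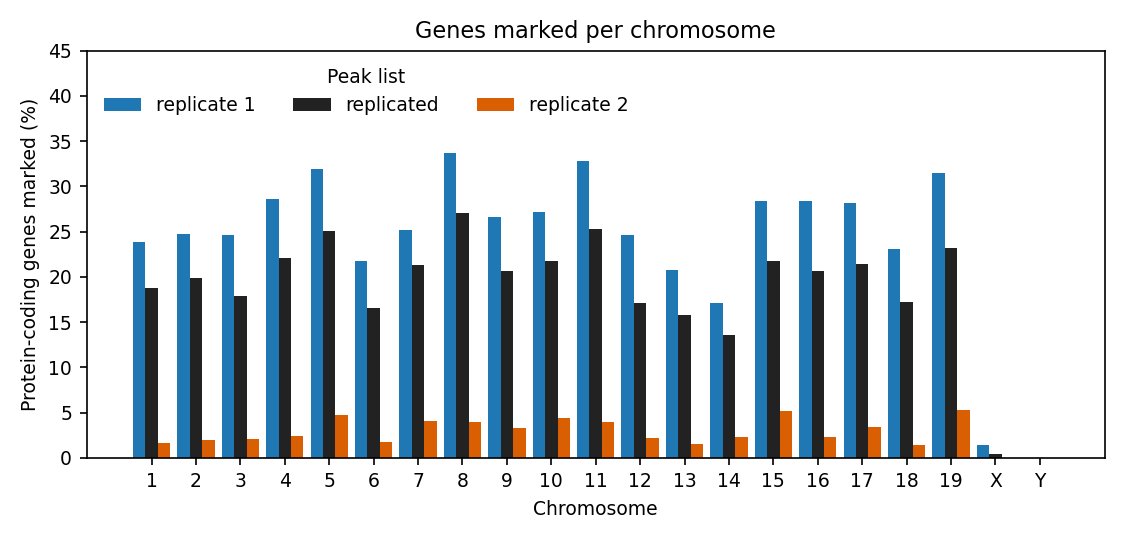
Protein-coding genes of at least 2 kb that are marked (%, y axis) on each chromosome (x axis), by replicate 1's list, the replicated list and replicate 2's list. Chromosome 8 has 27.1% marked in the replicated list, chromosome 14 has 13.6% and X has 0.379%.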

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

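Of the tests in this part, the comparison of signal values on the autosomes, the replicate 2 coverage of list members against matched genes, the use of peak midpoints, the random lists matched on length and GC content and the subsets of list members were chosen after the result was seen. The 8 replicated peaks on contigs outside chromosomes 1 to 19, X and Y belong to none of the comparisons and exceed the 3 that a count of 0 allows. The highest signal value among them was 5.44.

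Few X-linked genes were marked, 0.379% against 20.7% of autosomal genes. The tables argue against gene length and GC content as the cause: autosomal genes weighted to the length and GC classes of X-linked genes would be marked in 15.3% of cases, far above the upper limit of 1.10% for X. A lower dose of X against a fixed peak threshold stays open and is a candidate explanation, since in pooled males and females the active X is present in fewer copies than an autosome. In replicate 1, X held 0.508% of the peaks weaker than the median by deposited p and 0.368% of the stronger ones (two-sided Fisher's exact test, p = 0.000114). Only 0.711% of autosomal replicated peaks had a signal value of at least 2 times the list's 5th percentile (2.60). The number of replicated peaks per base of gene body on X was 3.27% of that on autosomes. The share of 0.711% rests on that cutoff, chosen after the result was seen. The lowest signal value of the list was 1.73 and the median 3.43. With the lowest value as the floor far more peaks would remain, so the share cannot decide the question. The X shares of replicate 1 go with a signal that falls under the threshold as a whole. The signal values do so only with that cutoff and if they scale with dose, which the lists do not state. Neither measures dose, and sexes were not separated, so no biological explanation was tested.

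Replicate 1 has several times more peaks than replicate 2. Lower sensitivity in replicate 2 stays open. The strongest 10% of replicate 1 peaks overlapped replicate 2 peaks 5.08 times as often as the weakest 10%, a rise that lower sensitivity would give. With peak midpoints, which do not gain from peak width, it was 4.84 times as often. Overlap could also rise with peak strength if the pools differed in some genes, so the ratio cannot separate the explanations. Whether a lower sensitivity may come from depth, enrichment or the further input entry of replicate 1 is not shown by peak lists. Different marking of some genes in the 2 tissue pools stays open too: the 28 cell cycle genes marked in replicate 1 had 2.87% covered in replicate 2 on average, against 4.60% for genes matched on replicate 1 covered share and length (adjusted permutation p = 0.0056), and the 155 Zfp genes had 6.94% against 5.19% (0.0016). Both also passed with matching on GC content or on the strongest peak in place of length, and the other 6 lists compared did not pass in any.

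Housekeeping lists were marked and most stomach cell type lists were not. The tables argue against GC content as the cause for the lists above chance, since 7 of 7 lists stayed past the threshold against random lists matched on length and GC content. It stays open that transcripts of cell types that are a small part of the organ fall under the peak threshold. Members of stomach lists held a replicate 1 peak in 44.4% of cases (99 of 223) and members of other-organ lists in 15.1% (28 of 185), a difference of 29.3 points (two-sided Fisher's exact test, p = 1.32e-10). Without smooth muscle and mesenchyme the shares were 31.4% and 15.1% (exact p = 0.00036), and among genes that overlap no other gene 34.8% and 9.18% (exact p = 4.15e-06). The cell makeup of the tissue was not measured, and a lower level of transcription within each cell may give the same values.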

How the results depend on the processing

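The alternatives with replicated peaks that overlap both replicates, GC-matched lists, autosomal genes only and shifts within 5 equal parts of the gene were chosen after the data were seen. Of the main results none changed direction. Of the gene lists 4 did in some settings, none past its threshold there: smooth muscle (9 marked, above chance) had 0 at a −log10 q of at least 5, mesenchyme (5, below) had 9 with the list of both replicates and at 5%, 10 with exons only and a median covered share of 0.7496%, and 0 to 9 with either replicate left out, enteroendocrine cells (1, below) had 1 to 1 with either left out, above chance without replicate 1, and cell cycle (21, above) had 4 with peaks that overlap both replicates and 0 to 28 with either left out. Replicate overlap, gene body share, profile, exon ratio and X difference stayed past their thresholds under all alternatives run, though at a −log10 q of at least 5 replicate 2 has only 2 peaks. The genes marked (4025) became 166 at a −log10 q of at least 5, 1997 at 20% of the body, 1806 among genes that overlap no other gene (fewer genes tested), 1906 with peaks that overlap both replicates, and 601 to 5181 with either replicate left out. The 7 lists above chance became 2 at a −log10 q of at least 5, 6 of the 7 stayed at 20% and with peaks that overlap both replicates (the cell cycle list was lost), and there were 4 to 8 with either replicate left out. The 4 lists below chance became 1 at that −log10 q, at 20%, among non-overlapping genes and with peaks that overlap both, 0 by median covered share, 12 with exons only, 13 with the list of both replicates and at 5%, 14 with GC matching, and 1 to 13 with either replicate left out. The muscle and epithelium difference of 24.4 points was 0 at a −log10 q of at least 5, where no gene of either side was marked, and 3.70 (exact p = 0.204) to 32.7 with either replicate left out. Where fewer genes could be marked or tested the construction shows the cause, and for the other changes the cause was not tested. Left-out ranges for the other results were 95.5% to 96.7% in gene bodies, 15.5 to 21.3 points for the profile, 1.75 to 1.77 for exons, and −25.3 to −3.10 points for X. No paired analysis was possible because there is only 1 group. Replicate overlap needs both replicates, so none was left out there. Unknown depth limits every count of unmarked genes.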

Other observations

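Of the tests in this part, all were chosen after the data were seen. Genes annotated as non-coding were rarely marked: 19 of 4962 lncRNA genes of at least 2 kb that lie clear of protein-coding genes (0.383%) passed the 10% rule, 23 in replicate 1 and 4 in replicate 2. The class was taken from the annotated gene type, with processed transcripts such as Tmem134 and Ifi30 among them, and lack of coding potential was not checked. Those named here were chosen after their values were seen. The most covered was Gm26917 on chromosome 17 (39843013 to 39846341, 87.9%), with 92.5% in replicate 1 and 73.4% in replicate 2. The deposited p of its peaks lay far from that of other peaks of like signal value (below), and the wider peak also overlaps the annotated gene CT010467.1. The lists do not show how reads of uncertain placement were treated, so this coverage may not reflect H3K36me3 at the gene. The hosts of small nucleolar RNAs with Snhg symbols among the 19 were Snhg17 on chromosome 2 (49.2%), Snhg12 (26.6%), Snhg1 (19.2%), Snhg15 (15.2%) and Snhg20 (10.3%), with 15.2%, 0%, 16.1%, 8.52% and 0% covered in replicate 2; whether such hosts were marked more often than other lncRNA genes was not tested. The nuclear RNA Malat1 on chromosome 19 (5795690 to 5802672) had 17.5% covered, 17.7% in replicate 1 and 6.01% in replicate 2. Among marked genes, the 138 zinc finger genes with Zfp symbols had a higher median share of exonic bases covered than the 3887 others, 40.04% against 31.06% (permutation test over genes with 10000 draws, two-sided p = 0.0002), while the medians for the whole gene body were 19.4% and 19.9%. Genes were not matched on where their exons lie, and coverage rises along the gene. The test therefore cannot tell a preference for exons from a difference in exon position.

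Housekeeping genes on X were not marked either. Of the 5 X-linked members of the housekeeping lists (Rps4x, Rpl10, Idh3g, Pdha1 and Pola1) 0 were marked, against 160 of 217 autosomal members (73.7%, two-sided Fisher's exact test, p = 0.00151). In replicate 1's list Rps4x had 8.35%, Idh3g 6.12% and Pdha1 5.28% of the body covered, below the 10% rule, while Pola1 had 0.0550% and Rpl10 had none. Rpl10 had 8.05% covered in replicate 2.

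Genes known to escape X inactivation had more replicate 1 coverage than X-linked genes of like length, which does not show that escape is the cause. Kdm5c and Eif2s3x, which are such genes, had been seen among the marked X-linked genes of replicate 1 before a list of 7 was made from general knowledge, so they were left out of the test. The 5 others (Kdm6a, Ddx3x, Pbdc1, Mid1 and Utp14a) had a median of 1.70% covered in replicate 1, against a mean of 0.0872% for random X-linked sets matched on length (permutation test with 10000 sets, two-sided p = 0.01). The sets were not matched on transcription, so the test cannot tell escape from a higher level of transcription. All 11 X-linked genes marked in replicate 1 exceeded the 5 there, and only Kdm5c (25.2%) and Eif2s3x (16.1%) of them are on the list. Those not on it included Flna (17.3%), Rbm3 (13.4%), Wdr13 (13.1%), Fam50a (12.7%), Hcfc1 (11.1%), Uba1 (10.4%) and Pqbp1 (10.2%). Irak1 (9.63%), not on the list and not marked, also exceeded the 5. None of the 5 reached 10% there. The test used replicate 1 only. Replicate 2 had no marked X-linked gene, and of the 5 it covered 2.38% of Ddx3x and 0.334% of Mid1, and 0% of Kdm6a, Pbdc1 and Utp14a.

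Of the 5 replicated peaks with the smallest deposited p, 4 were compared with other peaks within 0.1 of their signal value. They were picked for their p, so they had to lie high among these, and only the gap is of note. A peak of 355 bp in an intron of Cdk8 on chromosome 5 (146261101 to 146261455) had a −log10 p of 38.8 at a signal value of 5.58, where 68 other peaks reached at most 14.1. A pair of peaks over the lncRNA gene Gm26917 on chromosome 17 had 33.1 at 2.53 (39843897 to 39846524, 2283 others at most 6.23) and 20.7 at 2.06 (39843354 to 39843835, 306 others at most 3.36). The wider peak of this pair also overlaps the annotated gene CT010467.1, and how reads of uncertain placement were treated there is not shown. The peak from Mroh2a into Hjurp on chromosome 1 had 24.6 at 4.33, where 3852 others reached at most 10.5. The peak over Plec had 21.45 at 7.97, with 0 other peaks to compare.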
